A study of Mus musculus with 6 samples.

How the data were processed

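Kidney RNA of diabetic mice was profiled by sequencing of 6 libraries, 3 in each of 2 groups (WT/Sed and Cdo1KKO/Sed), each labelled as a separate biological replicate. Per the labels, diabetes was induced with streptozotocin, and poly(A) RNA was enriched from total RNA with oligo(dT) and made into libraries with the VAHTS Universal V6 kit. The labels do not spell out Sed and do not give batches, sequencing days, litters, ages or sexes. The authors' processing notes name fastp 0.23.4 and the mouse genome builds GRCm38 and mm10; the aligner, the counting tool, its annotation and the strandedness are not given in the sources used here. The authors deposited a table of counts per gene for 55401 gene identifiers and a table of TPM for the same genes. The deposited counts are whole numbers, and the deposited TPM values follow from the counts with 1 fixed length per gene and sum to the same total in every library. All 6 value columns were matched to libraries. Gene positions came from GENCODE release M21 (GRCm38), which holds 55141 of the identifiers.

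The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 17194; libraries were scaled by TMM; and Cdo1KKO/Sed was compared with WT/Sed by a robust quasi-likelihood F test with genotype as the only term. P values were adjusted over all genes tested by the method of Benjamini and Hochberg, with a threshold of 0.05. CPM values use the scaled library sizes. The libraries held 28145261 to 43872779 counts and 21993 to 24418 genes with at least 1 count. 3 counts over the 3 WT/Sed libraries, the upper limit that a count of 0 allows, equal 0.0281 CPM. Folds against 0 counts are given against this limit, and ratios against 1 to 3 counts with a 95% interval. The reads carry no molecular identifiers, so limits and intervals cover counting error only. The share of counts on each strand of overlapping genes, and between near-identical copies, is not known from counts per gene.

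46 lists of genes were fixed before the data were examined: 27 lists of functions and 19 lists of cell type markers. The function lists covered metabolism (sulfur amino acids with taurine and glutathione, fatty acid oxidation, synthesis of fatty acids and triglycerides with lipid droplets, cholesterol synthesis, AMPK and energy sensing, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, glycolysis with gluconeogenesis), stress and injury (ferroptosis, NRF2 targets with antioxidant defence, tubular injury, fibrosis with extracellular matrix, inflammation with chemokines, interferon response, unfolded protein and integrated stress responses, autophagy with lysosome, apoptosis with p53 targets, immediate early genes, heat shock response, hypoxia targets), transport (organic anions and drugs, and glucose with phosphate and sodium), the cell cycle, the circadian clock, and sex (male-biased, female-biased and Y-linked genes). The marker lists covered proximal tubule S1, proximal tubule S2 and S3, thin limb, thick ascending limb, distal convoluted tubule, collecting duct principal cells, intercalated cells, podocytes, endothelium, fibroblasts with pericytes and mesangium, macrophages with dendritic cells, neutrophils, T and NK cells, B and plasma cells, red blood cells, adipocytes, urothelium, adrenal cortex and medulla, and skeletal muscle. The rule for genes named in the text was fixed at the same time: Cdo1; the 10 largest fold changes in each direction among protein-coding genes with an adjusted p under the threshold, a mean of at least 1 CPM and no overlap between groups; and up to 4 members of each list with the smallest p. Named outside this rule, after their values were seen, were Alb, Arntl, Atg7, Bag3, Bhlhe40, Bhlhe41, Cenpe, Cldn16, Cry2, Csf1r, Cspg4, Ctsb, Ddit4, Errfi1, Fgb, Fkbp5, Gclc, Gclm, Gpx4, Gsr, Gsta4, Havcr1, Hbb-bs, Hk1, Hpx, Hsp90aa1, Hspa1a, Hspa1b, Kcnj1, Klf9, Krt19, Lcn2, Notch3, Nr4a2, Nsdhl, Pdk1, Per1, Pkm, Prkab1, Prkab2, Sgk1, Shmt2, Slc11a2, Slc12a1, Slc12a3, Slc34a1, Sqstm1, Stard4, Steap3, Tsc1, Tsc22d3, Txnrd1, Vdac2 and Zbtb16. Most of these complete a count of 5 or fewer members, and the others were singled out or belong to lists added later. Some genes that the rule selects, and some members that would complete a count, are not reported here. Lists were tested with camera in limma 3.58.1 on log-CPM values (prior count 2) with a preset correlation of 0.01, and also with an estimated correlation and with fry. GO and KEGG terms of 10 to 500 tested genes, as the deposited table assigns them, were tested for enrichment among genes that rose or fell. One-sided Fisher exact tests were used against all 17194 tested genes, of which 14293 had a term. Cdo1 was also compared by an exact permutation test of the CPM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

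Alternatives covered other scalings (RLE, upper quartile, library size only), DESeq2 1.42.0 and limma-voom in place of edgeR, no filter or a filter of 1 CPM in 3 libraries, the replicate number as a block, stricter thresholds, the TPM values with limma-trend (plus 1 or plus 0.1), leaving out mitochondrial and hemoglobin genes, and leaving out each library in turn. limma-voom with a weight per group, and the list counts without each library, were added after the data were seen.

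The steps were tested on simulated data of the same size. Among 16632 simulated genes without a difference, 4.98% had an unadjusted p under 0.05. Of 169 calls 20 were false (11.8%), above the nominal share. 44% of genes changed by 1.5-fold, 68% by 2-fold, 90% by 4-fold and 96% by 8-fold were recovered. The simulation changed 50 genes by each fold, far fewer than were called in the data, and gave both groups the same dispersion. Its shares of false calls and of recovered genes therefore need not hold for the data. Camera called 0 of 20 random lists, and the list made to change had an adjusted p of 3.6e-63. Genes were simulated independently, so this step could not test the preset correlation for lists whose genes vary together.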

Results

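Poly(A) RNA was sequenced from kidneys of mice made diabetic with streptozotocin, a toxin taken up by the insulin-producing beta cells of the pancreas. 2 groups of 3 libraries were compared, each library labelled as a separate biological replicate: WT/Sed, from wild-type mice, and Cdo1KKO/Sed, from mice of the genotype named Cdo1KKO. The labels do not spell out Sed. Cdo1 encodes cysteine dioxygenase, which oxidises cysteine to cysteine sulfinate, the first step towards taurine and sulfate. The stated purpose of the comparison was to find pathways that depend on Cdo1 of the renal tubule in diabetic kidneys. The libraries held 41261814, 28145261 and 43872779 counts in WT/Sed and 30711895, 37857672 and 43081847 in Cdo1KKO/Sed. Levels are given below as CPM (counts scaled to library size), mean ± SD of the 3 libraries of a group. Log2 fold changes are Cdo1KKO/Sed over WT/Sed ± an approximate SE. This SE is the absolute fold change on the log2 scale divided by the square root of the F statistic. It may be too small where a group holds few counts. A gene is said to have risen or fallen where its Benjamini-Hochberg adjusted p in the edgeR quasi-likelihood test was under 0.05. Members of a gene list named outside the 4 with the smallest p, most of them from counts of 5 or fewer, were chosen after their values were seen.

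Cdo1 itself (ENSMUSG00000033022.8) was lower in Cdo1KKO/Sed, but its transcript was still present in all 3 libraries. Its level was 184 ± 5.79 CPM in WT/Sed and 110.1 ± 7.94 CPM in Cdo1KKO/Sed, so that 59.8% of the WT/Sed level was counted (log2 fold change -0.74 ± 0.06, adjusted p = 4.64e-06). The WT/Sed libraries held 181, 191 and 180.5 CPM and the Cdo1KKO/Sed libraries 109, 118 and 103 CPM, without overlap. An exact 2-sided permutation test of the CPM gave p = 0.1, the smallest that 3 libraries against 3 allow. Cdo1 lies on the minus strand of chromosome 18, from 46713193 to 46728395 (GRCm38, GENCODE M21), and its principal transcript has 5 exons. A count per gene covers all of them, so it does not show whether a part of the transcript was missing, and kidney also holds cells other than tubule cells.

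Beyond Cdo1, the kidneys differed in expression of many genes. Of 17194 genes tested, 6435 changed (37.4%): 3250 rose and 3185 fell. The large changes were mostly increases, with 1163 genes at least 2-fold higher against 283 at least 2-fold lower, and 227 against 5 at 8-fold. The libraries of the groups did not overlap in 8642 genes (50.3%), where chance gives 10%. The first principal component separated the groups and held 68.1% of the variance, while the second (14.9%) set WT/Sed replicates 2 and 3 apart. The balance of rises and falls depended on the scaling. With library size as the only scaling, 5513 genes rose and 1685 fell (76.6% rises against 50.5%), and with the deposited TPM values 6714 rose and 1249 fell. These settings moved the median log2 fold change of all genes from 0.01 to 0.18 and 0.19, so changes are reported relative to the median gene. The Cdo1KKO/Sed libraries were closer to each other than the WT/Sed libraries, with a biological coefficient of variation per pair of 3.91% to 6.09% against 9.93% to 21%. All pairs differed by more than counting noise, the lowest chi-square per degree of freedom being 3.39.

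The largest increases were mostly in secreted acute-phase proteins, which the liver makes during inflammation. Serum amyloid A transcripts were almost absent from WT/Sed and abundant in Cdo1KKO/Sed. Saa1 reached 440.4 ± 16.7 CPM against 2 counts over the 3 WT/Sed libraries, a ratio of 23499.9 with a 95% counting interval of 6505 to 194052. Saa2, at 154 ± 16.4 CPM, was at least 5495-fold higher than the limit set by 0 counts in WT/Sed. Saa3 stood at 58.3 ± 5.59 CPM in Cdo1KKO/Sed against 0.0333 ± 0.0289 CPM in WT/Sed (log2 fold change 10.48 ± 0.21). With 4 counts over the 3 WT/Sed libraries, this approximate SE understates the uncertainty. The orosomucoids behaved alike: Orm1 was at least 1553-fold higher, Orm3 at least 95.3-fold, and Orm2 reached 174 ± 13.0 CPM against 2 counts, a ratio of 9282 (2569 to 76653). The serpins Serpina3m and Serpina3i were at least 229-fold and 87.1-fold higher, and the EGF receptor ligand Areg was at least 325-fold higher. The keratin Krt20 stood at 289 ± 38.1 CPM in Cdo1KKO/Sed against 0.411 ± 0.140 CPM in WT/Sed. These 10 genes had adjusted p values between 3.83e-12 and 6.76e-06. Saa1 (chromosome 7, 46740497 to 46742980) and Saa2 (46751790 to 46754313) are neighbouring copies, as are the Orm genes on chromosome 4 and the Serpina3 genes on chromosome 12, so the split of counts between members of a family is uncertain.

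The largest decreases were smaller. Grem1, an antagonist of bone morphogenetic proteins, fell from 5.41 ± 0.704 to 0.192 ± 0.0576 CPM (log2 fold change -4.83 ± 0.27, adjusted p = 2.92e-07). The growth hormone releasing hormone receptor Ghrhr fell by 3.29 on the log2 scale. Prkag3, a regulatory subunit of AMP-activated kinase, fell from 20.2 ± 2.72 to 3.66 ± 0.683 CPM, and the hormone Stc1 from 20.01 ± 1.57 to 3.97 ± 0.496 CPM. Others among the 10 largest were Fabp1, a fatty acid binding protein (-2.58 ± 0.56), the betaine transporter Slc6a12 (-2.41 ± 0.23), the carnitine synthesis enzyme Bbox1 (-2.12 ± 0.35), Ccdc3 (-2.10 ± 0.49) and Hif3a (-1.99 ± 0.20); the calls for Fabp1 and Ccdc3 ended with the TPM values on all genes. The adjusted p values of the genes named here ran from 1.26e-07 to 0.00799. WT/Sed replicates were uneven for Fabp1, at 2.80 ± 1.94 CPM.

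**Figure D1:**
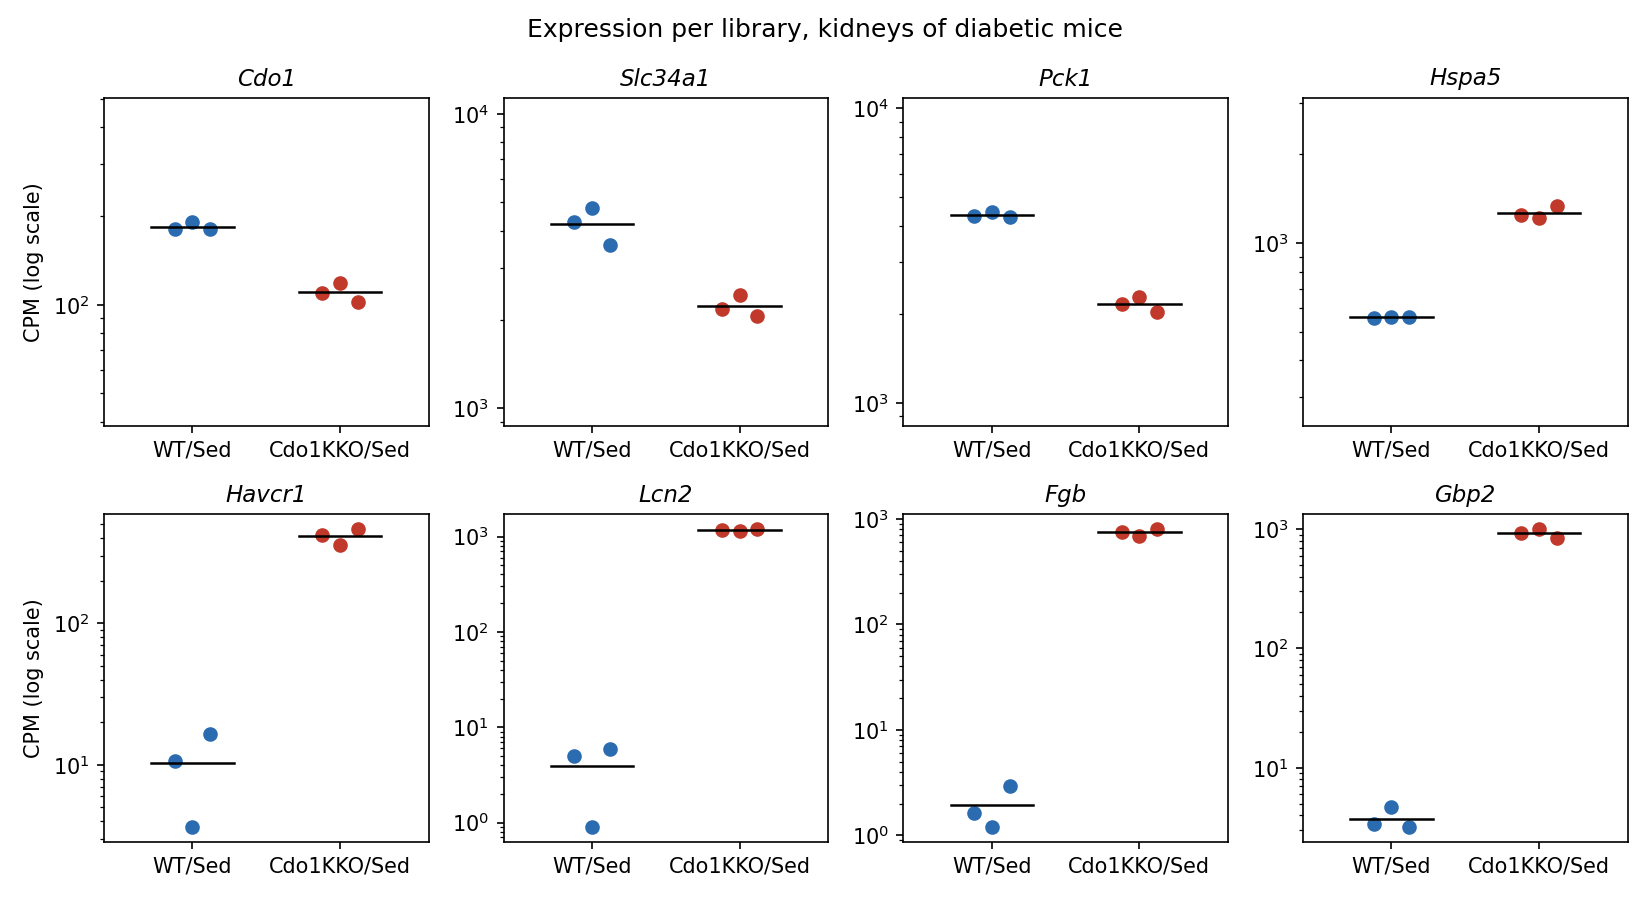
CPM of each library (y axis, log scale) for 8 genes in WT/Sed (blue) and Cdo1KKO/Sed (red), with 1 point per library and a line at the mean of each group. Cdo1, Slc34a1 and Pck1 are lower in all 3 Cdo1KKO/Sed libraries, and Hspa5, Havcr1, Lcn2, Fgb and Gbp2 are higher in all 3. Of these, Slc34a1, Havcr1, Lcn2 and Fgb were chosen after their values were seen.

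Genes that rise in injured tubules, and genes of inflammation, interferon signalling and extracellular matrix, were higher in Cdo1KKO/Sed. In the list of tubular injury genes, 27 of 30 members tested rose and 1 fell, the same counts as when adjusted over the list alone (camera adjusted p = 4.07e-15, adjusted p = 0.103 with an estimated correlation). The injury receptor Havcr1 (KIM-1), not among the 4 members with the smallest p and named after its values were seen, stood at 414 ± 52.6 CPM in Cdo1KKO/Sed against 10.2 ± 6.39 CPM in WT/Sed, and Lcn2 (NGAL), chosen likewise, at 1169 ± 27.7 CPM in Cdo1KKO/Sed against 3.96 ± 2.70 CPM in WT/Sed. By the fixed rule, the transcription factor Sox9 rose from 0.594 ± 0.129 to 41.4 ± 0.949 CPM, complement C3 to 400.1 ± 22.5 CPM (log2 fold change 4.74 ± 0.10), and fibrinogen alpha, Fga, to 2404 ± 34.1 CPM (4.96 ± 0.10). Krt19 was the member that fell, from 2.46 ± 0.765 to 1.02 ± 0.358 CPM; its call ended without WT/Sed replicate 1 (adjusted p = 0.0575) and with the TPM values plus 0.1 or on all genes. Of the inflammation and chemokine list, 26 of 30 rose (28 adjusted over the list alone; camera adjusted p = 2.36e-12, adjusted p = 0.103 with an estimated correlation), among them the neutrophil chemokine Cxcl2 at 19.1 ± 0.612 CPM in Cdo1KKO/Sed against 0.125 ± 0.0899 CPM in WT/Sed. Interferon response genes rose in 27 of 32 cases (30 adjusted over the list alone; camera adjusted p = 4.07e-15, adjusted p = 0.309 with an estimated correlation): the guanylate-binding protein genes Gbp2 and Gbp3 reached 921 ± 77.2 and 286 ± 17.1 CPM (log2 fold changes 7.97 ± 0.14 and 6.15 ± 0.08), and Ifit2 and Ifit3 rose by 2.34 ± 0.08 and 1.6 ± 0.07. The medians of these lists were 2.00, 2.08 and 2.35 on the log2 scale, the inflammation median being the same with Saa2 at its bound. The injury list holds acute-phase genes such as Lcn2, C3 and Fga, and the inflammation list holds the Saa genes named above. The rises of these lists and of the acute-phase genes therefore rest in part on the same genes. In the fibrosis and matrix list 23 of 35 rose and 1 fell (27 and 1 adjusted over the list alone; camera adjusted p = 8.94e-07, adjusted p = 0.446 with an estimated correlation). The metalloproteinase Mmp7 went from 0.0827 ± 0.0357 to 38.1 ± 4.55 CPM, Tgfbi rose by 1.85 ± 0.15 and decorin (Dcn) by 1.15 ± 0.10, while the basement membrane collagen Col4a3 fell to 306 ± 7.42 from 511 ± 15.0 CPM. In the same libraries 11 of 14 macrophage and dendritic cell markers, 7 of 8 neutrophil markers and 7 of 7 red blood cell markers rose.

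Transcripts of the proximal tubule, the segment that reabsorbs most of the filtered solutes, were lower, and so were those of organic anion and drug transport and of oxidative phosphorylation. Markers of the S1 segment fell in 9 of 10 cases (median log2 fold change -0.63; camera adjusted p = 1.24e-05, adjusted p = 0.103 with an estimated correlation) and markers of S2 and S3 in 8 of 10 (median -0.66; camera adjusted p = 1.58e-04, adjusted p = 0.183 with an estimated correlation), with the same counts adjusted over each list alone. The transcription factor Hnf4a fell from 828 ± 54.4 to 489.9 ± 16.5 CPM, Slc13a3 by 0.69 on the log2 scale, and the glucose transporter Slc5a2 (SGLT2) from 323 ± 9.71 to 229 ± 3.76 CPM. Of 18 organic anion and drug transporters, 15 fell (15 adjusted over the list alone; camera adjusted p = 9.31e-07, adjusted p = 0.133 with an estimated correlation), including the efflux transporter Slc47a1 (-0.88 ± 0.07), while 1 rose without WT/Sed replicate 3. The transporter list shares members with the S2 and S3 markers. Nuclear genes of oxidative phosphorylation fell in 32 of 33 cases, with a median of -0.40 (32 adjusted over the list alone; camera adjusted p = 2.37e-12, adjusted p = 0.308 with an estimated correlation). Cox5a fell by 0.56 and Atp5c1 by 0.45 on the log2 scale, and with the TPM values 20 genes of the list fell and 1 rose. Genes on the mitochondrial genome fell in 11 of 13 cases (11 adjusted over the list alone; camera adjusted p = 2.42e-06, adjusted p = 0.183 with an estimated correlation), and their share of all counts was 16.1% to 16.5% in WT/Sed and 13.9% to 14.3% in Cdo1KKO/Sed. With the TPM values 5 of them fell. In the fatty acid oxidation list 15 of 32 fell (15 adjusted over the list alone; camera adjusted p = 4.55e-06, adjusted p = 0.503 with an estimated correlation), with the acyl-CoA synthetase Slc27a2 at 3298 ± 154 CPM in Cdo1KKO/Sed against 6179 ± 48.6 CPM in WT/Sed. Without WT/Sed replicate 2, 30 of its members fell. The glycolysis and gluconeogenesis list went both ways, with 15 of 25 lower and 5 higher (15 and 5 adjusted over the list alone; camera adjusted p = 0.0104, adjusted p = 0.395 with an estimated correlation), and its median of -0.23 became 0.02 with the TPM values. Pck1, which controls gluconeogenesis, fell from 4347 ± 90.6 to 2167 ± 127 CPM. The glycolytic hexokinase Hk2 rose to 4.16 ± 0.457 from 0.261 ± 0.136 CPM and the glucose transporter Slc2a1 by 0.81 ± 0.06; Pkm, Pfkfb3 and Hk1 were the others that rose. Outside the proximal tubule, 5 of 8 markers of the distal convoluted tubule rose.

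Genes of sulfur amino acid metabolism, the pathway of Cdo1, were mostly lower. Of 27 members tested, Cdo1 included, 17 fell and 6 rose (17 and 7 adjusted over the list alone; camera adjusted p = 0.00510, adjusted p = 0.309 with an estimated correlation). The median log2 fold change was -0.49, against -0.63 and -0.66 for the S1 and the S2 and S3 markers of the proximal tubule. Cystathionine gamma-lyase Cth, which makes cysteine, fell from 192 ± 9.02 to 114 ± 1.48 CPM, and Csad, the enzyme after Cdo1 on the way to taurine, from 280.2 ± 7.05 to 170.4 ± 8.54 CPM. Against this direction, the methanethiol oxidase Selenbp1 rose to 868 ± 55.0 from 423 ± 35.7 CPM and the cystine importer Slc7a11 from 0.175 ± 0.0434 to 4.77 ± 1.29 CPM. Other members that rose were Gsr, Txnrd1, Gclc and Gclm, which were named after their values were seen and serve glutathione synthesis and thiol reduction (log2 fold changes 0.63 ± 0.05, 0.42 ± 0.05, 0.36 ± 0.09 and 0.17 ± 0.05). The call ended for Gclm without WT/Sed replicate 1 or Cdo1KKO/Sed replicates 1 or 3 (adjusted p 0.0518 to 0.0725). The list of NRF2 targets and antioxidant defence was split, with 17 of 33 higher and 10 lower (20 and 10 adjusted over the list alone; camera adjusted p = 0.0433, adjusted p = 0.309 with an estimated correlation). The metallothionein Mt1 rose from 31.8 ± 1.43 to 148 ± 11.5 CPM, and Pgd, G6pdx and Srxn1, which supply NADPH or reduce peroxiredoxins, rose by 0.97 ± 0.05, 0.87 ± 0.06 and 1.09 ± 0.08. The call for this list was lost without WT/Sed replicate 3 (adjusted p = 0.0889) and without Cdo1KKO/Sed replicate 1 (0.0510). It was also lost on ranks (0.0740), with a filter of 1 CPM (0.0615) and with the replicate block (0.0683). Among ferroptosis genes 12 of 23 rose and 4 fell (13 and 5 adjusted over the list alone; camera adjusted p = 0.00731, adjusted p = 0.308 with an estimated correlation). The transferrin receptor Tfrc rose by 1.13 ± 0.06, ferritin heavy chain Fth1 by 0.67 ± 0.04 and the polyamine acetyltransferase Sat1 by 0.62 ± 0.05. The members that fell were the lipid peroxide reductase Gpx4 (-0.32 ± 0.05), Steap3, Vdac2 and Slc11a2. With the TPM values 0 of the list fell, with library size only the calls for Vdac2 and Slc11a2 were lost, and the call was also lost for Slc11a2 without WT/Sed replicates 1 or 3 or any 1 Cdo1KKO/Sed library (adjusted p 0.0990 to 0.153).

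More members rose than fell in the lists of endoplasmic reticulum stress, p53 targets and immediate early genes. In the list of the unfolded protein and integrated stress responses, 20 of 29 rose and 2 fell (21 and 2 adjusted over the list alone; camera adjusted p = 4.55e-06, adjusted p = 0.103 with an estimated correlation). The chaperone Hspa5 (BiP) rose from 560.0 ± 2.58 to 1266 ± 64.7 CPM, and the transcription factors Xbp1 and Atf4 by 0.99 ± 0.05 and 1.08 ± 0.06, while Herpud1, a target of the same response, fell (-0.83 ± 0.05). The other member that fell was Shmt2, with the call lost without WT/Sed replicate 1 or any 1 Cdo1KKO/Sed library (adjusted p 0.0572 to 0.104), with upper-quartile factors, with library size only and with the TPM values, and 4 fell without WT/Sed replicate 2. Of the apoptosis and p53 target list 12 of 24 rose (12 adjusted over the list alone; camera adjusted p = 1.58e-04, adjusted p = 0.103 with an estimated correlation), with Cdkn1a (p21) at 51.3 ± 0.587 CPM in Cdo1KKO/Sed against 15.9 ± 1.39 CPM in WT/Sed, and Gdf15, Aen and Btg2 higher by 2.36 ± 0.12, 0.76 ± 0.07 and 1.35 ± 0.13. None of that list fell with all libraries and 1 fell without WT/Sed replicate 2 or WT/Sed replicate 3. Immediate early genes rose in 12 of 21 cases and fell in 2 (12 and 2 adjusted over the list alone; camera adjusted p = 0.00387, adjusted p = 0.503 with an estimated correlation). Egr1, Junb and Ier2 rose by 1.77 ± 0.11, 1.39 ± 0.11 and 1.39 ± 0.12. The phosphatase gene Dusp1 had the smallest p of that list and fell to 43.95 ± 3.23 from 126 ± 7.05 CPM, Nr4a2 being the other that fell, and 5 fell without WT/Sed replicate 3.

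Lists of other metabolic functions did not pass as a whole, although many members changed. The lists of lipid synthesis and lipid droplets (11 of 28 higher, 7 lower, camera adjusted p = 0.497), cholesterol synthesis (6 of 22 higher, 5 lower, adjusted p = 0.885) and AMPK and energy sensing (5 of 26 higher, 8 lower, adjusted p = 0.334) held changes in both directions. The lipid droplet protein Plin2 rose from 81.1 ± 7.01 to 901 ± 103 CPM and Plin4 by 2.50 ± 0.14, with the fatty acid synthesis enzymes Scd2 and Acly higher by 0.80 ± 0.06 and 0.49 ± 0.05. The median of the lipid list was -0.01 and its mean 0.21, and camera's direction was higher. Msmo1 and Idi1 of sterol synthesis rose (0.71 ± 0.06 and 0.66 ± 0.06), while genes that fell included Hmgcs1, Cyp51, Nsdhl and Stard4, Hmgcs1 and Cyp51 by 0.68 and 0.49 on the log2 scale. Nsdhl and Stard4 did not pass with library size only or with the TPM values. The call was also lost for Stard4 without WT/Sed replicate 1 or any 1 Cdo1KKO/Sed library (adjusted p 0.0644 to 0.0774). In the AMPK list the mitochondrial deacetylase Sirt3 and the transcription factor Foxo3 fell (-0.91 ± 0.06 and -0.81 ± 0.11), and Sesn3 (0.71 ± 0.07), Camkk2 (0.54 ± 0.10), Tsc1, Prkab2 and Prkab1 rose, the call being lost for Prkab1 without Cdo1KKO/Sed replicates 1 or 2 (adjusted p 0.0511 and 0.0722). Without Cdo1KKO/Sed replicate 1 or Cdo1KKO/Sed replicate 3, 5 members of that list and 3 of the cholesterol list fell, as did 3 of the latter without WT/Sed replicate 1. Of the genes of glucose, phosphate and sodium transport 7 of 29 rose and 12 fell (adjusted p = 0.175). The phosphate cotransporter Slc34a2 rose from 3.44 ± 0.626 to 67.3 ± 2.85 CPM, while the fructose transporter Slc2a5 fell by 1.28 and the angiotensin-converting enzyme Ace by 0.74 on the log2 scale. Hypoxia targets (4 of 19 higher, 8 lower, adjusted p = 0.333) had a median of -0.14 and a mean of 0.10, with camera's direction lower. Slc2a1, Hk2, Pfkfb3 and Pdk1 rose and Ldha, which makes lactate, fell from 609 ± 15.9 to 448 ± 10.7 CPM; the call was lost for Pdk1 without WT/Sed replicate 1 or Cdo1KKO/Sed replicates 1 or 2 (adjusted p 0.0543 to 0.0779). Autophagy and lysosome genes rose in 4 of 28 cases and fell in 10 (adjusted p = 0.125): the protease Ctsl rose from 696 ± 20.3 to 1416 ± 67.4 CPM, and Sqstm1, Ctsb and Atg7 rose as well, the call being lost for Atg7 without WT/Sed replicate 2 or any 1 Cdo1KKO/Sed library (adjusted p 0.0548 to 0.140). Adjusted over the list alone, the counts higher and lower were 11 and 8 for lipid synthesis, 6 and 6 for cholesterol, 5 and 8 for AMPK, 7 and 12 for transport, 4 and 8 for hypoxia, and 4 and 10 for autophagy. The medians of these lists were between -0.16 and 0.01, and with library size as the only scaling all 6 were above 0.

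Clock, heat shock and cell cycle lists did not pass either. Clock genes rose in 5 of 20 cases and fell in 9 (adjusted p = 0.432; 7 and 10 adjusted over the list alone), with 8 higher without WT/Sed replicate 3. Usp2, Hlf and Tef, which are outputs of the clock, fell by 1.23, 0.97 and 1.22 on the log2 scale. Npas2 (1.05 ± 0.11), Arntl, Bhlhe41, Bhlhe40 and Cry2 rose, with the call lost for Cry2 without Cdo1KKO/Sed replicate 3 (adjusted p = 0.0729). Heat shock genes rose in 5 of 14 cases and fell in 6 (adjusted p = 0.789, direction lower; median -0.05, mean 0.15; 5 and 6 adjusted over the list alone). The small heat shock protein Hspb1 rose from 3.46 ± 0.730 to 20.1 ± 1.70 CPM, and Bag3, Hspa1b, Hsp90aa1 and Hspa1a rose as well, while the related Cryab fell from 121 ± 9.93 to 76.2 ± 1.84 CPM. The call was lost for Hspa1a without WT/Sed replicates 1 or 3 or Cdo1KKO/Sed replicates 1 or 3 (adjusted p 0.0501 to 0.110). Of 31 cell cycle genes 4 rose and 1 fell (adjusted p = 0.252; 0 and 1 adjusted over the list alone). They were Mcm3, Pcna, Birc5 and Cenpe, which rose, and Kif23, which fell (-0.71 ± 0.15) but not with the TPM values. Calls were lost for Mcm3 without Cdo1KKO/Sed replicates 1 or 2 (adjusted p 0.0547 and 0.0917), Pcna without WT/Sed replicate 1 or any 1 Cdo1KKO/Sed library (adjusted p 0.0504 to 0.0903), Birc5 without WT/Sed replicates 1 or 2 or any 1 Cdo1KKO/Sed library (adjusted p 0.0606 to 0.101) and Cenpe without WT/Sed replicates 2 or 3 or Cdo1KKO/Sed replicates 1 or 2 (adjusted p 0.0556 to 0.166). 2 of the list fell without WT/Sed replicate 2. The medians of the clock and heat shock lists were above 0 with library size as the only scaling.

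**Figure D2:**
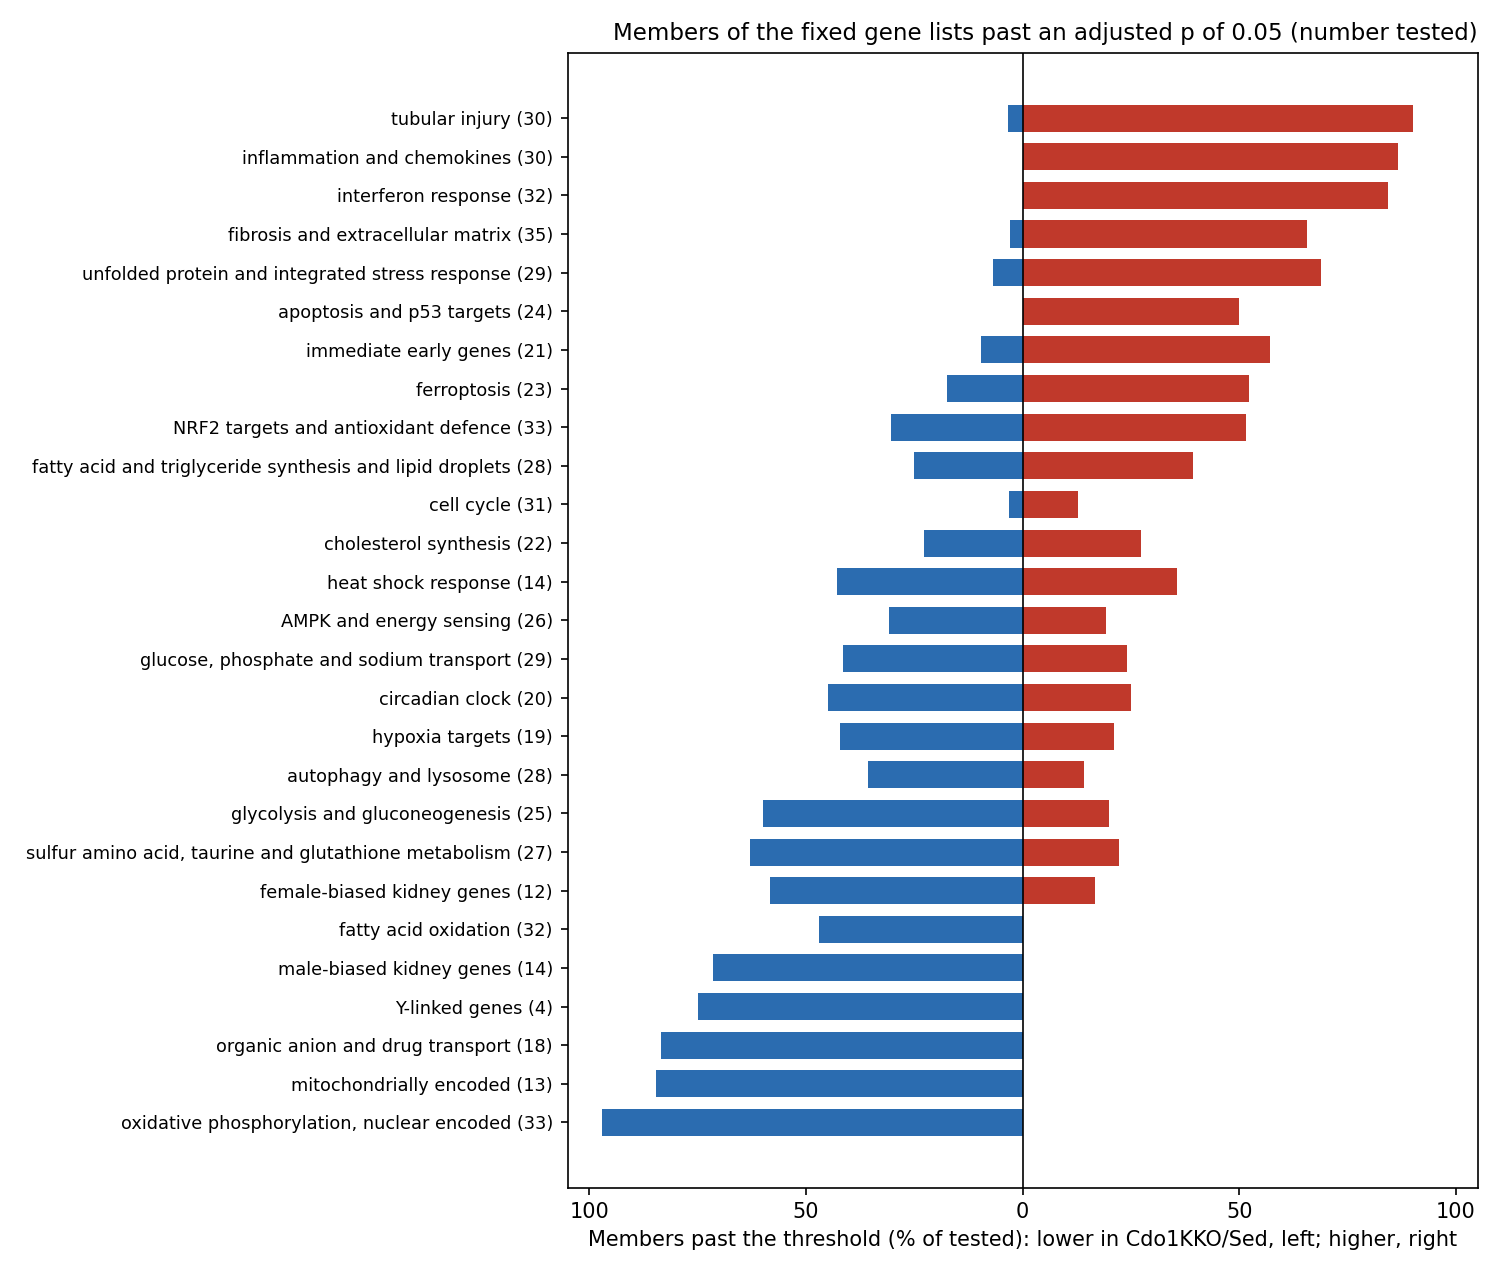
Share of the tested members of each of 27 gene lists (y axis, number tested in brackets) that passed the threshold, in percent (x axis), with falls in Cdo1KKO/Sed to the left in blue and rises to the right in red. The tubular injury list has 27 of 30 members to the right, and the list of nuclear oxidative phosphorylation genes 32 of 33 to the left.

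Kidney genes known to differ between the sexes were mostly lower, whichever sex they favour. Male-biased genes fell in 10 of 14 cases (11 adjusted over the list alone; camera adjusted p = 5.35e-05, adjusted p = 0.309 with an estimated correlation), such as Cyp2e1 (-0.77 ± 0.07) and Serpina1f (-0.73 ± 0.08). Female-biased genes fell in 7 of 12 and rose in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0210, adjusted p = 0.503 with an estimated correlation), with Sult1d1 at 1135 ± 23.8 CPM in Cdo1KKO/Sed against 2377 ± 302 CPM in WT/Sed and the exporter Abcc3 higher by 1.56 ± 0.22. Gsta4 was the other member that rose. The medians were -0.51 and -0.85, against -0.63 and -0.66 for the 2 lists of proximal tubule markers. The list of S2 and S3 markers shares members with both sex-biased lists, so it is not a separate yardstick. Of 4 Y-linked genes Eif2s3y (-0.31 ± 0.06), Kdm5d (-0.30 ± 0.06) and Uty (-0.28 ± 0.08) fell, also adjusted over the list alone (3). With library size as the only scaling, or with the TPM values, 0 of them passed, and the call was lost for Uty without Cdo1KKO/Sed replicates 1 or 2 (adjusted p 0.0538 and 0.0691). The list test gave an adjusted p of 0.0961, and of 0.0488 without WT/Sed replicate 2.

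Markers of other cell types differed between the groups as well. Macrophage and dendritic cell markers rose in 11 of 14 cases and fell in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 1.58e-04, adjusted p = 0.503 with an estimated correlation), with Cd14 at 281 ± 13.2 CPM in Cdo1KKO/Sed against 3.83 ± 1.00 CPM in WT/Sed and Cd68 and Itgam higher by 3.16 ± 0.29 and 3.15 ± 0.24. Leaving out WT/Sed replicate 1 or any 1 Cdo1KKO/Sed library left 6 higher. Csf1r was the member that fell (-0.33 ± 0.09), with the call lost without Cdo1KKO/Sed replicate 1 (adjusted p = 0.0563), with library size only and with the TPM values. Neutrophil markers rose in 7 of 8 (7 adjusted over the list alone; camera adjusted p = 7.27e-05, adjusted p = 0.309 with an estimated correlation), at low levels such as 7.60 ± 1.02 CPM in Cdo1KKO/Sed against 0.591 ± 0.317 CPM in WT/Sed for S100a9. All 7 red blood cell markers rose, also adjusted over the list alone (camera adjusted p = 6.96e-06, adjusted p = 0.309 with an estimated correlation). The beta globin transcript Hbb-bs, named after its value was seen, stood at 284 ± 7.15 CPM in Cdo1KKO/Sed against 28.4 ± 9.70 CPM in WT/Sed, and Alas2, the heme synthesis enzyme of erythroid cells, at 18.7 ± 1.17 CPM in Cdo1KKO/Sed against 1.33 ± 0.186 CPM in WT/Sed. Hemoglobin genes are near-identical copies, and the count of each is uncertain. Along the nephron, distal convoluted tubule markers rose in 5 of 8 cases, with the same count adjusted over the list alone (median 0.48; camera adjusted p = 0.00711, adjusted p = 0.446 with an estimated correlation), namely Slc8a1 (1.53 ± 0.06), Trpm6 (1.01 ± 0.08), Calb1 (0.83 ± 0.07), Tmem52b and Slc12a3, and 1 fell without WT/Sed replicate 3. The lists of the thin limb (1 of 8 higher, 3 lower), thick ascending limb (5 of 10 higher, 2 lower), collecting duct principal cell (3 of 10 lower), intercalated cell (3 of 10 higher, 1 lower) and podocyte (1 of 10 higher, 3 lower) had camera adjusted p values of 0.383, 0.367, 0.189, 0.313 and 0.257. Adjusted over each list alone, the counts were the same except for 6 higher in the thick ascending limb and 4 higher in intercalated cells. The medians of the thin limb and principal cell lists turned above 0 with library size as the only scaling, and that of the podocyte list with the TPM values.

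The water channels Aqp2, Aqp3 and Aqp4 were the principal cell genes that fell, Aqp2 from 293 ± 24.8 to 107 ± 0.841 CPM, and 1 principal cell gene rose without WT/Sed replicate 2. Aqp1, the water channel of the thin limb and proximal tubule, fell by 1.25 on the log2 scale, Cryab and Akr1b3 being the other thin limb genes that fell and Bst1 (0.55 ± 0.12) the one that rose. With the TPM values the calls for Akr1b3 and for the genes Cldn16, Cdkn1c and Wt1 were lost. In the thick ascending limb Umod, the most abundant protein of normal urine, rose to 2377 ± 73.0 from 1417 ± 222 CPM, and Egf (0.51 ± 0.05), Sostdc1, Kcnj1 and Slc12a1 rose, while Ppp1r1a (-0.69 ± 0.05) and Cldn16 fell. The call was lost for Slc12a1 without Cdo1KKO/Sed replicate 3 (adjusted p = 0.0524). Intercalated cell genes that rose were Slc4a1 (0.98 ± 0.08), which red blood cells share, Aqp6 and Atp6v0d2, and Slc4a9 fell (-0.56 ± 0.10); the call was lost for Atp6v0d2 without WT/Sed replicate 1 or Cdo1KKO/Sed replicate 3 (adjusted p 0.0597 and 0.0599). Without WT/Sed replicate 2, 5 intercalated cell genes rose, and 2 fell without WT/Sed replicate 3. Of podocyte genes Tcf21 rose (1.02 ± 0.22) and those that fell included Cdkn1c and Wt1, with calls lost for Cdkn1c without WT/Sed replicate 1 or Cdo1KKO/Sed replicates 2 or 3 (adjusted p 0.0503 to 0.0511) and Wt1 without Cdo1KKO/Sed replicates 1 or 3 (adjusted p 0.0512 and 0.0566), and 1 fell without Cdo1KKO/Sed replicate 3. The podocyte list passed without WT/Sed replicate 3 (adjusted p = 0.0356).

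The fibroblast, pericyte and mesangium list had 5 of 12 higher and 1 lower, also adjusted over the list alone, with an adjusted p of 0.0633 and 0.0194 without WT/Sed replicate 2. 3 of its members rose without WT/Sed replicate 1, Cdo1KKO/Sed replicate 2 or Cdo1KKO/Sed replicate 3. Dcn and the platelet-derived growth factor receptors Pdgfra and Pdgfrb rose (1.15 ± 0.10, 1.27 ± 0.19 and 1.11 ± 0.22), as did Notch3 and Cspg4, while the renin gene Ren1 fell (-1.27 ± 0.25). Calls were lost for Notch3 without WT/Sed replicate 1 or any 1 Cdo1KKO/Sed library (adjusted p 0.0521 to 0.0910) and Cspg4 without WT/Sed replicates 1 or 3 or Cdo1KKO/Sed replicates 2 or 3 (adjusted p 0.0506 to 0.142). B and plasma cell markers rose in 4 of 9 cases, among them Derl3 (4.14 ± 0.29), Ms4a1 and Ighm, also adjusted over the list alone (adjusted p = 0.0963), and in 2 without WT/Sed replicate 1 or any 1 Cdo1KKO/Sed library; 2 fell without WT/Sed replicate 3. Calls were lost for Ms4a1 with the TPM values plus 1 and without WT/Sed replicates 1 or 3 or Cdo1KKO/Sed replicates 1 or 2 (adjusted p 0.0740 to 0.163), and for Ighm without WT/Sed replicate 1 or any 1 Cdo1KKO/Sed library (adjusted p 0.0958 to 0.130). The list passed without WT/Sed replicate 1 (0.0429) or WT/Sed replicate 2 (0.0237). No member of the endothelial list (12 tested), the T and NK cell list (10), the urothelial list (6) or the 1 adrenal gene tested passed in edgeR, with 0 at an unadjusted p under 0.05 and 0 in DESeq2, while limma-voom called 5 endothelial genes. The list tests gave adjusted p values of 0.216, 0.266 and 0.641. Without WT/Sed replicate 2, 1 endothelial and 1 T and NK cell gene rose and 2 urothelial genes fell, while 1 endothelial gene fell without WT/Sed replicate 3. Endothelial genes passed as a list without WT/Sed replicate 2 (0.00966), as did the urothelial list (0.0365) and the adipocyte list (0.0339, against 0.189 with all libraries). Of 3 adipocyte markers tested 1 rose, Cidec (3.15 ± 0.34), also adjusted over the list alone, and 2 rose without WT/Sed replicate 2. Cidec is also in the list of lipid synthesis and lipid droplets, so its rise need not mean adipocytes. Skeletal muscle markers were too low to be tested.

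**Figure D3:**
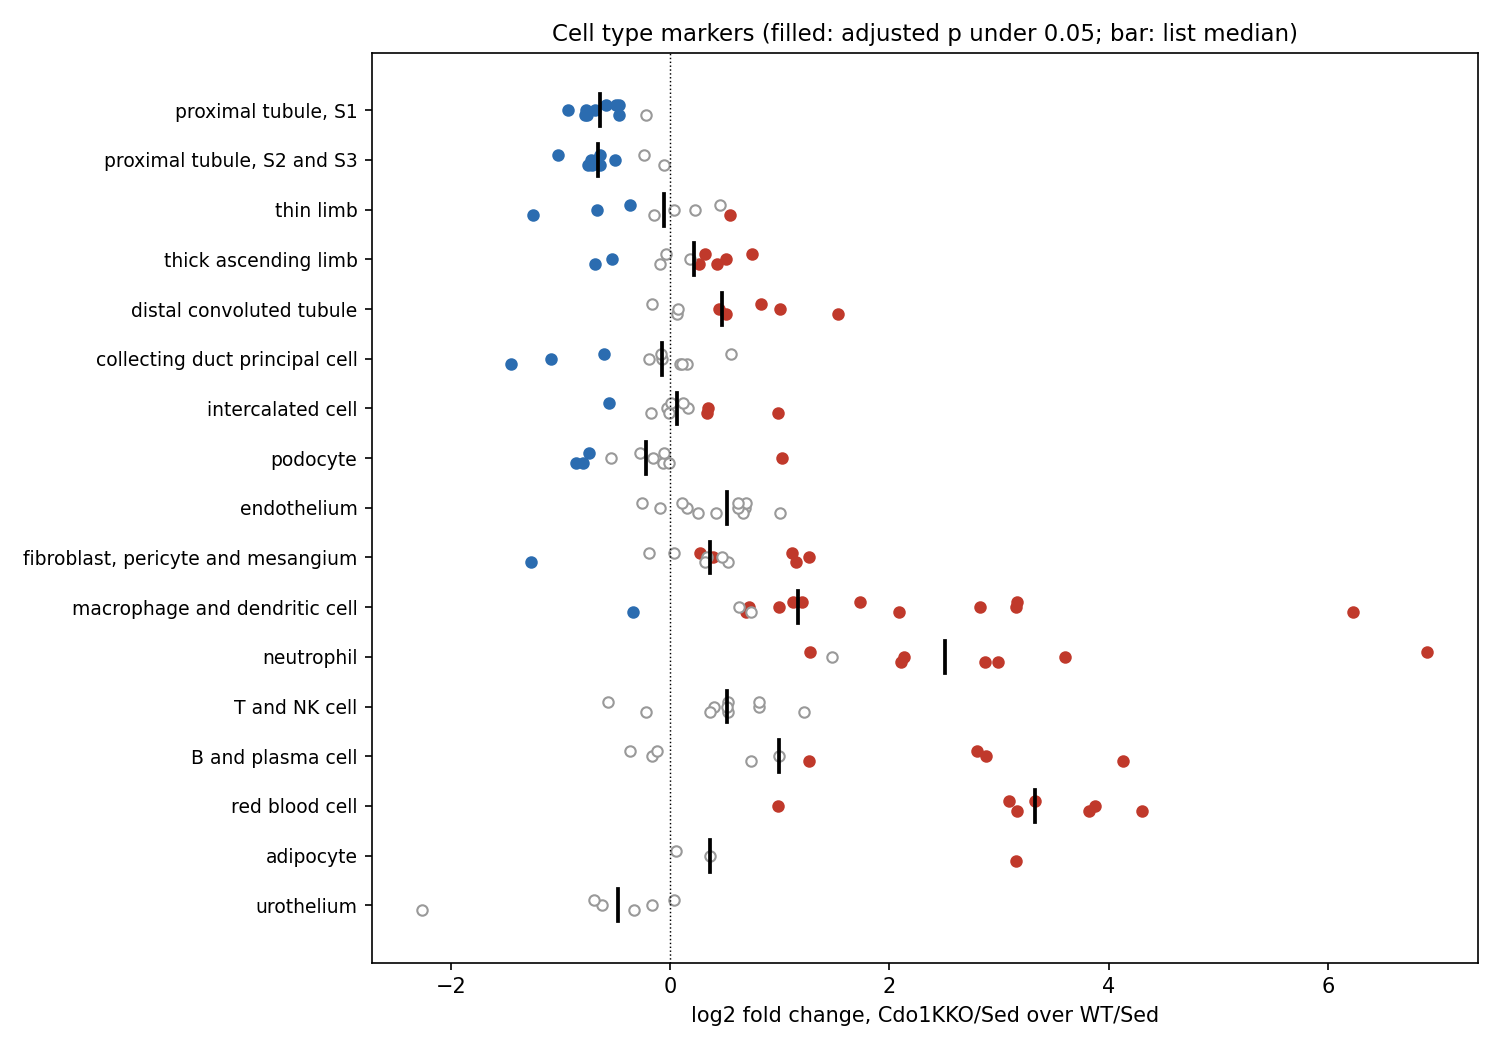
log2 fold change of each tested marker (x axis) by cell type list (y axis), with points filled in red for rises, filled in blue for falls and open where the adjusted p was 0.05 or more, and a bar at the median of each list. The proximal tubule medians lie at -0.63 and -0.66, the distal convoluted tubule median at 0.48, and the red blood cell median at 3.33.

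Terms for mitochondria and amino acid breakdown were enriched among the genes that fell, and terms for immune responses and adhesion among those that rose. Of 7790 GO and KEGG terms given in the deposited table and tested in each direction, 2202 were enriched among the genes that rose and 689 among those that fell (one-sided Fisher exact test, adjusted p under 0.05). Genes that fell included 241 of 389 tested genes against 72.1 expected for the mitochondrial inner membrane (adjusted p = 9.76e-78) and 32 of 43 tested genes against 7.97 expected for degradation of branched-chain amino acids (adjusted p = 1.86e-13). Peroxisome genes fell in 45 of 77 cases against 14.3 expected (adjusted p = 6.02e-13), and citrate cycle genes in 23 of 29 against 5.37 (adjusted p = 1.09e-10). Among the genes that rose, 228 of 453 tested genes against 85.6 expected belonged to the response to bacterium (adjusted p = 2.02e-49), 136 of 269 tested genes against 50.8 expected to leukocyte migration (adjusted p = 3.42e-29), and 77 of 181 tested genes against 34.2 expected to focal adhesion (adjusted p = 1.07e-11).

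Of 44 lists tested, 23 passed camera with its preset correlation, 13 higher and 10 lower. 0 passed with an estimated correlation, where 8 had an unadjusted p under 0.05, and 33 passed fry, which does not compare a list with other genes. Splits of the libraries that mix the groups gave 8 to 20 lists with camera's preset correlation, although 0 genes changed in them. The p values of lists with the preset correlation may therefore be too small.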

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

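The voom fit with a weight per group was the only alternative here chosen after the results were seen, besides the list counts without each library. Depth and 3 libraries per group limit the small changes. In simulated data with far fewer changed genes, 44% of 1.5-fold changes were recovered, a share that need not hold here. The number of changed genes was 6086 to 6888 with the other tools, filters and factors that adjust for composition, with the replicate block and without mitochondrial and hemoglobin genes, against 6435. With library size only, 5513 rose and 1685 fell. With the TPM values plus 1 on the same genes 6714 rose and 1249 fell, plus 0.1 6617 and 1240, and on all genes above 0 5588 and 1019. These settings do not correct for the composition of the libraries, and the median log2 fold change of all genes moved to 0.18, 0.19, 0.25 and 0.09. A threshold of 0.01 left 4184 (2098 higher, 2086 lower) and a further minimum of 2-fold at 0.05 left 1446 (1163 and 283), as stricter thresholds must. Leaving out 1 library at a time gave 4682 to 7320 changed genes, 2306 to 3767 higher and 2331 to 3553 lower, a log2 fold change of Cdo1 of -0.80 to -0.70, 22 to 29 lists and 2737 to 3261 terms. The log2 fold change of Cdo1 was below 0 and past the threshold in every alternative run, the closest to 0 being -0.49 with the TPM values. Replicate numbers do not pair the groups, with correlations of -0.00, 0.01 and 0.01 between libraries of the same number, and with them as a block 6146 genes changed. With an estimated correlation 0 lists passed camera, with 8 at an unadjusted p under 0.05, and fry passed 33; the cause was not tested. Lists that passed fry but not camera, with fry's adjusted p, were lipid synthesis and droplets (0.00775), autophagy and lysosome (0.0227), circadian clock (0.00351), glucose, phosphate and sodium transport (0.00557), Y-linked genes (0.0375), thin limb (0.00775), collecting duct principal cell (3.21e-04), fibroblast, pericyte and mesangium (0.0287), B and plasma cell (0.0346), adipocyte (0.0196). NRF2 targets had an adjusted p of 0.0683 with the replicate block. With terms of 20 to 300 genes 2287 terms passed, and with genes at an unadjusted p under 0.01 2897. Among genes named, the log2 fold changes of Alb, Vdac2 and Slc11a2 changed sign with the TPM values, to 0.0542, 2.88e-04 and 0.0714 plus 1, 0.0609, 2.91e-04 and 0.0736 plus 0.1, and 0.0542, 2.88e-04 and 0.0714 on all genes. So did Per1 (0.0554, 0.0577 and 0.0554) and Ddit4 (0.219, 0.225 and 0.219), Ddit4 also with library size only (0.0753), limma-voom (0.0227), voom with group weights (0.0257) and without WT/Sed replicate 2 (0.252), against -0.33 without WT/Sed replicate 3. Calls ended with the replicate block for Birc5, Ighm, Ren1, Sgk1 and Slc11a2, with upper-quartile factors for Ighm and Shmt2, with DESeq2 for Cspg4, Ms4a1 and Slc11a2, with limma-voom for Cenpe (with group weights too) and Slc11a2, without a filter for Sgk1 and with a filter of 1 CPM for Slc11a2. Per1 fell past the threshold without a filter. With library size only calls ended for Csf1r, Eif2s3y, Kdm5d, Nsdhl, Shmt2, Slc11a2, Stard4, Uty and Vdac2. With the TPM values plus 1 on the same genes they ended for Akr1b3, Cdkn1c, Cldn16, Csf1r, Eif2s3y, Gpx4, Kdm5d, Kif23, Klf9, Ms4a1, Nsdhl, Shmt2, Stard4, Steap3, Uty and Wt1. Plus 0.1 they ended for those except Ms4a1, and for Krt19. On all genes above 0 they ended for all of these and for Aqp4, Ccdc3, Cenpe, Errfi1, Fabp1, Nr4a2 and Slc4a9.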

Other observations

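Of the tests in this part, those over other splits of the libraries were planned; the others were chosen only after the results were seen, and so were the lists of hepatocyte, acute-phase and glucocorticoid-induced genes. Genes that glucocorticoids induce in many tissues were lower in Cdo1KKO/Sed. Of 10 listed, 9 were tested, 4 of which other lists hold as well, and 7 fell (camera p = 5.10e-05, p = 0.0209 with an estimated correlation, both unadjusted). As the list was made after the results were seen, these p values are no independent test of it. Tsc22d3 (GILZ), a direct target of the glucocorticoid receptor, fell from 56.8 ± 3.26 to 27.9 ± 2.20 CPM, and Fkbp5, which restrains the receptor, from 199 ± 19.7 to 112 ± 2.20 CPM. On the log2 scale Zbtb16 fell by 1.83, Dusp1 by 1.52 and Errfi1 by 0.61, and Klf9 fell by 0.53 but not past the threshold with the TPM values, nor did Errfi1 with those on all genes. Sgk1 fell by 1.71, with the call lost without WT/Sed replicate 1 or any 1 Cdo1KKO/Sed library (adjusted p 0.0603 to 0.0734). Ddit4 and Per1 did not pass (adjusted p = 0.849 and 0.0948), though Per1 fell past the threshold without Cdo1KKO/Sed replicate 2 (adjusted p = 0.0108).

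Markers of vessels and glomeruli varied among the WT/Sed libraries. The mean log2 CPM of the endothelial markers was 4.11, 4.81 and 2.99 in WT/Sed replicates 1, 2 and 3, against 4.50 to 4.57 in Cdo1KKO/Sed. For podocyte markers it was 4.41, 4.72 and 3.95, against 4.10 to 4.19. Markers of the S1 proximal tubule ran from 9.59 to 9.74 in WT/Sed and 9.03 to 9.10 in Cdo1KKO/Sed, without overlap.

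Markers of the proximal tubule had a median log2 fold change of -0.66, and Cdo1 fell by 0.74. A lower share of proximal tubule cells as the only change would raise the markers of all other segments alike. The distal convoluted tubule score minus the principal cell score went from 2.18 ± 0.12 to 2.96 ± 0.02, a difference of 0.783. So a lower share was not the only change along the nephron. Changes of expression within the other segments would move this difference too, so it does not bear on the proximal fall itself. A lower share alone would lower all proximal tubule markers alike, but the 20 markers ran from -1.02 to -0.05. For markers made only in proximal tubule cells, this argues against a lower share as the whole cause. It may still be a part of the cause. The choice of TMM did not make this fall, as with library size only the upper quartile of the proximal tubule markers was still -0.319. Both scalings give levels relative to the library, so a fall in absolute amount was not tested. Deletion of Cdo1 beyond the fall of these markers stays open: 6 of 20 proximal tubule markers fell further than Cdo1 (range -1.02 to -0.05). The lower Cdo1 count may come from the deletion, from lower expression of proximal tubule genes in general, from a lower share of proximal tubule cells, or from several of these.

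Acute-phase genes were higher in Cdo1KKO/Sed in 19 of 19 cases tested, of 20 listed, 10 of the tested genes being in other lists too. The list was made after the results were seen. It holds the Saa, Orm and Serpina3 genes already named among the largest increases, so this count is no separate support. Liver RNA in the Cdo1KKO/Sed libraries is argued against: hepatocyte genes, 13 of 20 of which kidney libraries held above the filter, had a median log2 fold change of -0.64, and Alb stood at 6.03 ± 0.823 CPM against 440.4 ± 16.7 for Saa1. Among hepatocyte genes 1 rose, Hpx, at 3.01 ± 0.890 CPM. The difference in genotype stays among the open explanations, as untested.

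The Cdo1KKO/Sed libraries were closer to each other than the WT/Sed libraries. That 1 library was deposited more than once is argued against by the lowest chi-square per degree of freedom of a pair, 3.39, above the value near 1 that counting noise gives. Repeat libraries of 1 RNA sample or pool stay open: the endothelial score had a range of 0.0663 among Cdo1KKO/Sed libraries and 1.82 among WT/Sed libraries, which mice that vary less could also give. If the Cdo1KKO/Sed libraries came from a pool, the tests would rest on fewer animals than libraries.

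The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05, the smallest share being 0.1. The real split gave 6435 changed genes and the highest other split 0 by edgeR, with 7884 and at most 379 at an unadjusted p under 0.05, and 1 split in 10 gave as many. Every other split mixes the groups, so the group difference enters the spread within each side and makes calls of genes and terms unlikely. The counts of those splits are therefore no reference for libraries without a difference. For terms the real split gave 2891 and the highest other 0. For lists it gave 23 and the others 8 to 20, although 0 genes passed in those. A mixed split keeps part of the group difference, so these lists need not be false. Still, list p values with the preset correlation may be too small.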
